A study of Mus musculus with 14 samples.

How the data were processed

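The data are 7 narrow-peak lists from ChIP-seq of E14 mouse embryonic stem cells, each called on the 2 pooled libraries of a group, 14 libraries in all. Per the labels' protocols, cells received 1 µM doxorubicin or DMSO for 6 h, were kept in drug-free medium for another 6 h, harvested 12 h after the start and fixed with 1% formaldehyde for 10 min. The titles of the HA libraries do not say whether those cells had received doxorubicin, so their treatment is left open here. Both p53 libraries carry the same replicate number in their titles and were numbered only to name them.

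Reads were aligned with Bowtie2 2.2.6, per the submitters' processing notes, to mm10 with an added contig, per the file headers. Peaks were called by the authors with MACS 2.2.5 in paired-end mode with 1 fragment kept per position and a q cutoff of 0.05, per the file headers. The 4 histone lists and the input list were called without a control against a genome-wide background. The untagged list was called against the input with a genome-wide background and the p53 list against the same input with a local background, per the file headers. The signal in the deposited lists is the pileup of fragments at a summit, and in the HA lists it had been scaled to the depth of the input. The deposited q values are given as −log10. The fold enrichment in the deposited lists is the ratio of the pileup to the background, as MACS computed it. Lengths are in bp as deposited.

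Summits of the same interval were joined into 1 region that took the values of its highest summit. Lists were compared by overlap of at least 1 bp, with chance levels from 100 random placements of the regions within their chromosomes. For the p53 regions, moving each by 10000 bp to either side gave a further background. Shares carry 95% Wilson intervals. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 on 82177 simulated regions, with 0 differing. In simulated lists the planted shares were recovered, which checks the counting only, since the way the lists were built fixed that outcome. Of 200 unrelated lists of 50 genes, 5 had fewer than 5% of random lists with as many p53 genes.

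Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 45039 protein-coding, long non-coding and pseudogene entries. The table gives no strand or exons, so the planned distance to a transcription start was replaced by the distance to either annotated gene end, and promoters, exons and introns are not told apart. A gene counted as having a region when it lay within 1000 bp of an end. The 16 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. Random lists, 10000 per gene list, matched gene class, and for p53 also vehicle H3K27ac. They drew genes singly and do not reflect clusters of neighbouring genes. Named genes were the 25 nearest to the p53 regions of highest −log10 q, within 5000 bp and with no untagged or input region, the 10 protein-coding genes with the treatment-only histone regions of highest fold enrichment in each direction, and members of the gene lists with a p53 region or a mark in 1 treatment only. Other genes in the closing part were chosen after their values were seen.

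A common depth-scaled cut-off, added after the data were seen, kept regions with a summit pileup of at least 1 fragment per 1000000 fragments of the list. Alternatives covered stricter −log10 q and fold enrichment, the overlap required, merging of regions, equal list lengths, the input regions, the chromosomes and the gene window. Since each list pools its replicates, no test across replicates was run and no p-values are given. Repeat annotation, a genome sequence and motif searches were not used here.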

Results

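Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in E14 mouse embryonic stem cells exposed to doxorubicin, a topoisomerase II poison that breaks DNA, or to the DMSO vehicle. The 14 libraries fall into 7 groups of 2. H3K27ac, a histone mark of active promoters and enhancers, and H3K9me3, a mark of heterochromatin, were each profiled after vehicle and after doxorubicin. The other groups are an HA ChIP from cells with HA-tagged p53, an HA ChIP from cells without the tag, and input chromatin from doxorubicin-treated cells. Each group is represented by 1 peak list called on its pooled libraries, so none of the comparisons has a replicate check, and the intervals given are 95% Wilson intervals that cover counting error only. Fragments left after removal of duplicates numbered 20647895 for vehicle H3K27ac, 17036528 for doxorubicin H3K27ac, 15992125 for vehicle H3K9me3 and 14402634 for doxorubicin H3K9me3. The p53 ChIP had 45238471, the untagged ChIP 49588950 and the input 16583331. Fold enrichments are the authors' own values for the highest summit of a region and serve here only to describe or rank regions within a list.

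The p53 ChIP addresses where the tagged protein sits in the genome, with the untagged ChIP as the background of the antibody. Regions were found at long-established p53 target genes. At Cdkn1a, which encodes the cell cycle inhibitor p21, a region on chromosome 17 from 29090508 to 29092240 (mm10) covered the gene end at 29090979 with a fold enrichment of 64.2. Ccng1, the pro-apoptotic genes Bbc3 and Bax, and Mdm2, whose product degrades p53, had regions within 1000 bp of a gene end with fold enrichments of 35.4, 32.5, 23.5 and 17.9. Of 50 p53 target genes listed before the data were examined, 26 had a p53 region within 1000 bp of either gene end, against a median of 2 in 10000 random lists matched on gene class and vehicle H3K27ac, and 0 of those lists reached as many. Within 5000 bp the number was 32.

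The p53 list held 11282 regions covering 5.61 Mb. Of these, 417 (3.70%) overlapped a region of the untagged list, against 0.396% for randomly placed regions, and 10865 did not. The median fold enrichment was 7.76 for regions absent from the untagged list and 3.12 for those present in it. The input list held 199 of the p53 regions (1.76%) and 35.6% of the untagged regions. Summits of 8.03% of the p53 regions lay within 1000 bp of a gene end, against 5.90% in a random placement. Elsewhere within a gene lay 49.1%, and 42.9% lay outside annotated genes. Fold enrichment was at least 100 at 186 of the 10865 regions. The p53 and untagged lists share the input as control but were called with different background settings. The number of regions in each and their shares in the input list are therefore not compared. The overlap between the 2 lists may also depend on these settings.

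The strongest p53 regions were not those of the target gene list. None of the 25 genes nearest to the strongest regions, within 5000 bp of a summit and with no untagged or input region, was among the 50 target genes. Their fold enrichments ran from 99.3 to 369. The rule left out some stronger regions that overlapped an untagged region, such as that within Adamts2 with a fold enrichment of 926. It also left out strong regions with no gene end within 5000 bp, such as those within Rbms3 and Tubgcp3, with 458 and 378. The last of the 25 genes belonged to the region ranked 84 among those without an untagged or input region. Among the 25, the highest were beside Zscan20, on chromosome 4 from 128575229 to 128576610, and within Cyp4f39, on chromosome 17 from 32456553 to 32457930, where the value was 359. Mrps31, which encodes a mitochondrial ribosomal protein, had a region with a fold enrichment of 273, Rgcc 248, Zfp61 227 and Ndufa7, which encodes a subunit of respiratory complex I, 206. Eed, a core subunit of Polycomb repressive complex 2, had 173, Alkbh3 151, Syt11 148, Zkscan4 131, Zmynd8 124, Alg14 119 and Muc13 104. Of the 25 genes, 15 are annotated as protein-coding, and the others, such as Gm5232, Gm30028 and Gm35343, as pseudogenes or long non-coding RNAs. All 25 regions overlapped H3K27ac in the doxorubicin list and 22 did so in the vehicle list. H3K9me3 was listed at 18 of them in vehicle and 22 in doxorubicin.

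**Figure D1:**
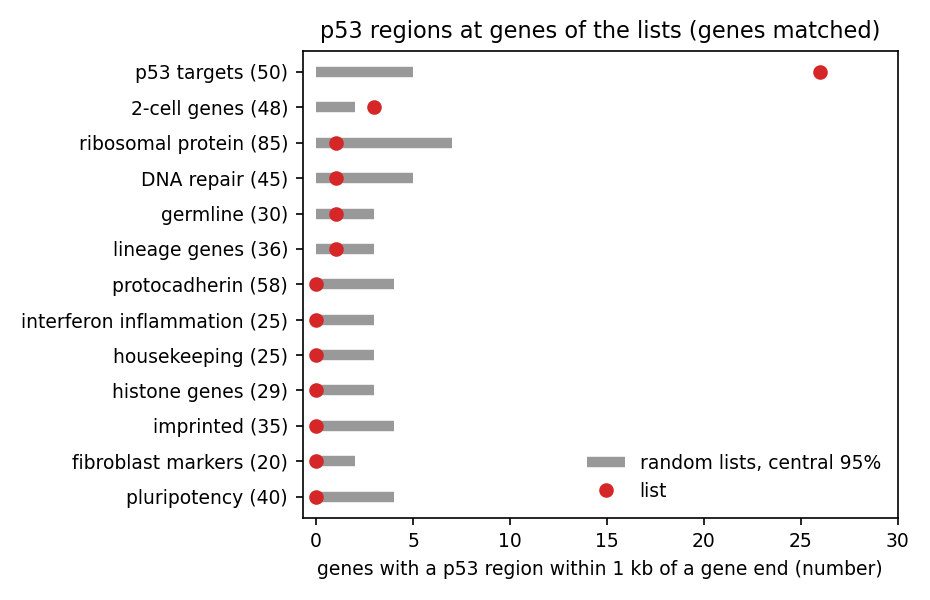
Number of genes with a p53 region within 1 kb of a gene end (horizontal axis) for gene lists of up to 85 matched genes, with the number of genes matched in parentheses. Points are the lists and grey bars the central 95% of 10000 random lists; the p53 targets stand at 26 genes against a random range of 0 to 5.

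Outside the target list, p53 regions near gene ends were few in every list examined. The list of genes of the 2-cell-like state, a rare state of embryonic stem cells that resembles the 2-cell embryo, had 3 of 48 matched genes, Zfp750, Tdpoz2 and Tdpoz5, where 247 of 10000 random lists reached as many. The untagged ChIP, called with other settings, had regions at 4 of the 48. None of 40 pluripotency genes had a p53 region within 1000 bp, while 5 had one within 5000 bp, among them Sox2 and Klf4, with fold enrichments of 6.11 and 7.52. The lineage list had 1 gene, Afp, and the germ-line list 1, Hormad1. Zinc finger genes of the Zfp family had 9 of 372, against a random median of 12.

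The H3K27ac lists ask which regions carry the active mark only after doxorubicin. Most genes of the pluripotent state were listed with the mark in both treatments. Of 40 pluripotency genes, 36 had a region within 1000 bp of a gene end in vehicle and 35 in doxorubicin. In both treatments 43 of 45 DNA repair genes and 29 of 29 histone genes had one. These counts give presence in a list only, and the amount of the mark at these genes was not compared. Doxorubicin-only regions of highest fold enrichment at protein-coding genes were at Ano3, a member of the anoctamin family, Nudt18, Prpf6, which encodes a splicing factor, Wdhd1, Zscan30, Tusc2, Foxn1, a transcription factor of the thymic epithelium, Mgll, Tbcel and Ttc16, with values of 10.4 to 12.9. A p53 region overlapped 5 of these 10, those at Ano3, Prpf6, Wdhd1, Foxn1 and Mgll. Over all 52232 doxorubicin-only H3K27ac regions the share at a p53 region was 5.99%. Vehicle-only regions of highest fold enrichment were at Sfi1 and Eif4enif1, H1f0 and Gcat, Zbtb14, Cep43, Fxr1, Zfp292, and Atxn7l2 and Sypl2, with values of 10.0 to 12.5, and 0 of these 10 genes had a p53 region there.

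The doxorubicin list held 112259 regions and the vehicle list 82177. Of the vehicle regions 71.2% were found in doxorubicin, and of the doxorubicin regions 53.5% were found in vehicle, against 8.47% and 6.39% for random placement. This left 52232 doxorubicin-only and 23695 vehicle-only regions. With the same number of top regions taken from both lists the ratio of doxorubicin-only to vehicle-only regions was 0.991, an outcome that equal lengths build in. Of the 8217 vehicle regions of highest −log10 q 99.6% were found in doxorubicin, and of the 11225 such doxorubicin regions 98.5% were found in vehicle. Within genes lay 64.7% of the doxorubicin-only summits and 51.5% of the vehicle-only summits, and at gene ends 11.1% and 13.6%.

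Gene groups differed in how many members carried H3K27ac in only 1 treatment. Among the p53 targets, Perp and Fas were in the doxorubicin list only and Trp73 in the vehicle list only. Among the 48 genes of the 2-cell-like state, 4 were in doxorubicin only (Duxf3, Arg2, Tdpoz2 and Tdpoz5), and the median was 4 in random lists matched on gene class and 8 in lists matched also on the vehicle state. Lineage regulators had 7 in doxorubicin only, Gata6, Cdx2, Hnf4a, Mesp1, Hoxb1, Zic1 and Dnmt3b, a number that 332 of 10000 random lists matched on gene class reached and 326 of those matched also on the vehicle state, and 4 in vehicle only, Sox17, Hand1, Neurog1 and T, which 556 and 426 such lists reached. Imprinted genes had 5 in doxorubicin only, H19, Grb10, Mest, Magel2 and Nap1l5, which 1845 and 205 random lists reached. They had 4 in vehicle only, Dlk1, Nnat, Ndn and Usp29, which 552 and 1685 reached. The vehicle region counted for Usp29, with a fold enrichment of 27.7, is also that of Peg3. A doxorubicin region at Peg3, with a fold enrichment of 11.8, overlaps it but ends just outside the window of Usp29. Usp29 thus counts as vehicle only because of the window, and the mark was listed there in both treatments. Dppa4 was in doxorubicin only and Lin28a and Dppa3 in vehicle only. Markers of fibroblasts, which feed other cultures of these cells, had 5 in doxorubicin only, Thy1, Fbn1, Col6a2, Snai2 and Twist2, which 229 and 1490 random lists reached. Olfactory receptor genes had 24 of 1116 in doxorubicin only, below the medians of 96 and 196 in random lists. The counts of the 2-cell-like, lineage, imprinted and fibroblast lists depended on the settings. At a −log10 q of at least 5, genes of the 2-cell-like state had 1 gene in doxorubicin only and 0 in vehicle only, lineage regulators 1 and 4, imprinted genes 4 and 2, and fibroblast markers 1 and 1. With equal numbers of top regions, lineage regulators had 3 and 6 and imprinted genes 4 and 5. Within 2500 bp of a gene end genes of the 2-cell-like state had 7 and 0 and imprinted genes 3 and 1. Within 500 bp lineage regulators had 7 and 7, imprinted genes 7 and 5, and fibroblast markers 3 and 1. The match on the vehicle state was added after the data had been seen, and with 16 lists compared in each mark these numbers are not corrected for how many were looked at.

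**Figure D2:**
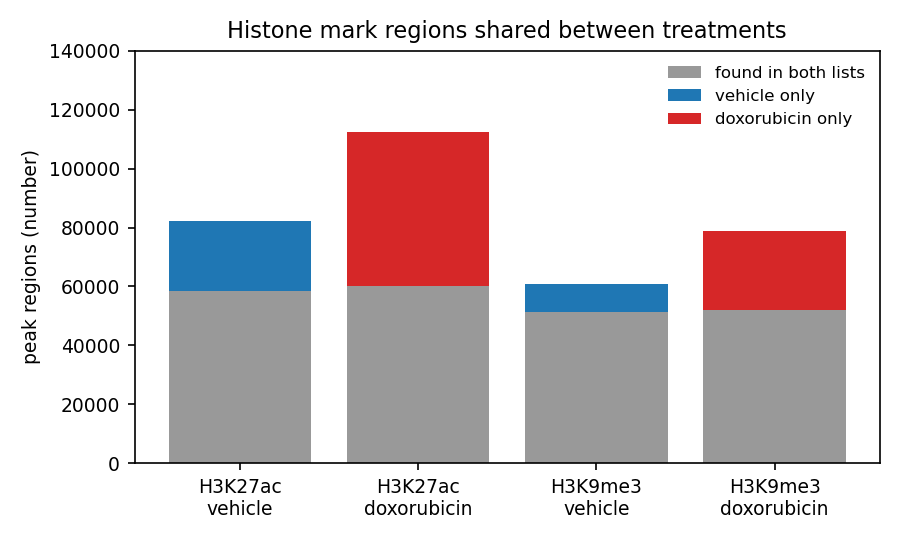
Number of peak regions (vertical axis) in the 4 histone lists, split into those found in both treatments (grey), vehicle only (blue) and doxorubicin only (red). Doxorubicin-only regions number 52232 for H3K27ac and 27061 for H3K9me3, against 23695 and 9487 in vehicle only.

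The H3K9me3 lists ask the same question of heterochromatin. Zinc finger genes of the Zfp family, many of which lie in H3K9me3-marked clusters, had the mark within 1000 bp of a gene end at 74 of 372 genes in vehicle and 82 in doxorubicin, against a random median of 22 in vehicle. Genes of the 2-cell-like state had it at 10 of 48 in vehicle, which 7 of 10000 random lists reached. That list holds clusters of neighbouring genes, such as Tdpoz2, Tdpoz3 and Tdpoz4 on chromosome 3, which all had the mark in vehicle. Random lists drew genes singly, so the count may be less unusual than 7 of 10000 implies. Pramel11, Zscan4-ps1 and Zscan4e carried H3K9me3 in doxorubicin only and Gm5662 and Tdpoz2 in vehicle only. Olfactory receptor genes with the mark numbered 24 in vehicle and 48 in doxorubicin, and vomeronasal receptor genes 22 and 32. The 27 olfactory receptor genes with the mark in doxorubicin only compare with a median of 27 in random lists of the same gene class.

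Doxorubicin-only H3K9me3 regions of highest fold enrichment at protein-coding genes were at Zfp61, Lamtor3-ps, Vmn2r33, Defb28, Flt1, which encodes a VEGF receptor, Vmn2r44, Galnt6, Wsb1, Cthrc1 and Olfr175, with values of 8.02 to 10.8. Those at Zfp61 and Defb28 overlapped a p53 region, as did 2.02% of all doxorubicin-only H3K9me3 regions. Vehicle-only regions were at Obi1, Shcbp1, the imprinted gene Igf2r, Samt1c, Fam71a, the histone gene H2bc4, Tiam1, Slc25a46, Gcnt3 and Sp110, with values of 5.52 to 7.47, and 0 of these overlapped a p53 region. Sp110 had H3K9me3 in doxorubicin at its other gene end, from 85609787 to 85610722, with a fold enrichment of 9.07. The doxorubicin list held 78890 regions and the vehicle list 60836, of which 65.7% and 84.4% were found in the other list, against 4.79% and 6.06% by chance. Doxorubicin-only regions numbered 27061 and vehicle-only regions 9487, a ratio of 2.85. With equal numbers of top regions the ratio was 1.03, again an outcome that equal lengths build in. Gene ends held 4.67% of vehicle and 5.14% of doxorubicin summits, against 5.75% and 5.77% in a random placement. Outside genes lay 64.9% and 65.8% of the summits.

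Whether the marks differ at p53 regions was asked with the 10865 regions absent from the untagged list. H3K27ac was listed at 41.3% of them in vehicle (40.4 to 42.2) and 71.7% in doxorubicin (70.9 to 72.5). It was in doxorubicin only at 3361 regions (30.9%) and in vehicle only at 55 (0.506%), or 61.1 to 1. The same regions moved by 10 kb to either side, a background added after the data had been seen, had 9.36% in vehicle and 12.9% in doxorubicin, and 2.67 doxorubicin-only for each vehicle-only. In the 2716 p53 regions of highest −log10 q the shares were 59.1% and 88.1%, and in the 2717 of lowest −log10 q 32.3% and 60.5%. Regions at gene ends had the mark in 57.2% and 84.0%, those elsewhere in genes in 45.9% and 76.3%, and those outside genes in 33.0% and 64.1%. Of the 25 genes nearest to the strongest p53 regions, Rgcc, Cyp4f39 and Olfr1123 had H3K27ac at that region in doxorubicin only. With equal numbers of top H3K27ac regions, 27.0% of p53 regions were in doxorubicin only and 0.727% in vehicle only.

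H3K9me3 was listed at 17.8% of the p53 regions in vehicle and 23.0% in doxorubicin. It was in doxorubicin only at 637 regions (5.86%), among them those at Zfp61, C1rb, Ndufa7 and Gm30028, and in vehicle only at 63 (0.580%), a ratio of 10.1. Regions moved by 10 kb had 4.35% and 5.37%, with a ratio of 2.78. The 2716 strongest p53 regions had the mark in 35.9% and 45.1%. From the next strongest to the weakest group the shares were 9.54%, 7.88% and 17.8% in vehicle and 14.5%, 11.2% and 21.4% in doxorubicin. Of p53 regions outside genes, 25.7% had the mark in vehicle and 32.4% in doxorubicin. With equal numbers of top H3K9me3 regions the share in doxorubicin only was 3.80% and that in vehicle only 1.01%.

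**Figure D3:**
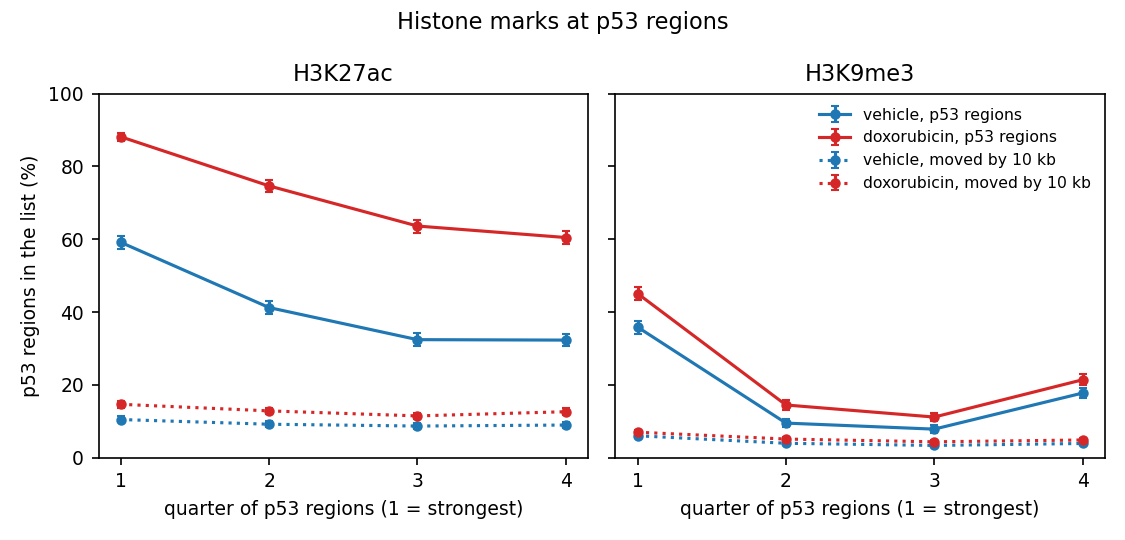
Share of p53 regions (vertical axis, percent) that overlap H3K27ac (left) or H3K9me3 (right) in vehicle (blue) and doxorubicin (red), for 4 equal groups of the p53 list ranked by −log10 q with 1 the strongest; dotted lines are the same regions moved by 10 kb and bars are 95% Wilson intervals. H3K27ac in the strongest group goes from 59.1% to 88.1%.

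The Dux locus, which encodes an activator of the 2-cell-like state, and a contig added to the mm10 assembly were examined in every list. Within 50000 bp of Duxf3, at 58229505 to 58233089 on chromosome 10, the 7 lists held 1 region, an H3K27ac region in doxorubicin from 58231919 to 58232654 with a fold enrichment of 3.45 and a −log10 q of 3.20. It is absent when a −log10 q of at least 5 is required. On the contig tig00005009, whose origin is not given in the sources used here, p53 had 20 regions, of which the strongest, from 795962 to 797621, had a fold enrichment of 132. H3K27ac overlapped 12 of the 20 in vehicle and 18 in doxorubicin. The contig held 149 H3K27ac regions in vehicle and 247 in doxorubicin, 58 and 92 of H3K9me3, 2 of the untagged ChIP and 0 of the input.

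H3K27ac and H3K9me3 shared few regions. In vehicle 8.95% of H3K27ac regions overlapped H3K9me3, against 4.67% by random placement, and in doxorubicin 9.07% against 5.46%. The input list held 1.59% of H3K27ac regions in vehicle and 1.13% in doxorubicin, and 2.28% and 1.72% of H3K9me3 regions.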

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

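Alternatives with a depth-scaled pileup cut-off of 1 fragment per 1000000 or a merging distance of 5000 bp were added after seeing the data; the others were planned. No paired analysis was possible because each list pools its replicates, and leaving out a replicate could not be run for the same reason. The excess of doxorubicin-only over vehicle-only regions held under each alternative but equal list lengths, where the ratio was 0.991 for H3K27ac and 1.03 for H3K9me3, an outcome that equal lengths build in. At the depth-scaled cut-off the H3K9me3 ratio was 4.68. The counts themselves moved. For H3K27ac, doxorubicin-only and vehicle-only regions were 21542 and 12729 at a −log10 q of at least 5, 25580 and 14155 at a fold of at least 4, 13572 and 5947 at the depth-scaled cut-off, and 19459 and 7350 after merging within 5000 bp. Equal lengths gave 29919 doxorubicin-only, and merging within 1000 bp 14938 vehicle-only regions. For H3K9me3, vehicle-only regions were 4987 at the stricter q, 5818 at the stricter fold and 5897 after merging within 1000 bp. Doxorubicin-only and vehicle-only regions were 14649 and 3128 at the depth-scaled cut-off, and 11379 and 4065 after merging within 5000 bp. Equal lengths gave 14437 doxorubicin-only regions.

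The number of p53 regions without an untagged region kept within 1.5 times under each of its alternatives. The shares of p53 regions with a mark in vehicle or in doxorubicin moved more often. Of 24 such values, 20 left the Wilson interval of the reported share and 4 did not. With the stricter q for histones the vehicle and doxorubicin shares were 29.9% and 60.3% for H3K27ac, and 14.5% and 19.6% for H3K9me3. The doxorubicin share stayed above the vehicle share in each setting. Doxorubicin-only H3K27ac was at 30.0% of all p53 regions and at 27.0% with equal lengths, and vehicle-only H3K27ac at 0.285% with the stricter q for histones and 0.727% with equal lengths. Equal lengths gave 3.80% and 1.01% for H3K9me3. For genes of the 2-cell-like state, H3K27ac in doxorubicin only was at 7 genes within 2500 bp and 1 at the stricter q, and vehicle H3K9me3 at 17 within 2500 bp. Summits within 2500 bp of a gene end were 31.0% for H3K27ac in vehicle, 28.1% in doxorubicin, 10.8% and 11.3% for H3K9me3, 17.5% for p53, 26.3% for the untagged ChIP and 29.3% for input. At the stricter q the shares within 1000 bp were 24.8% and 21.4% for H3K27ac, 4.43% and 4.81% for H3K9me3, and 16.3% for the untagged ChIP. Contig regions at the stricter q were 74 and 100 for H3K27ac and 34 and 52 for H3K9me3, and those near Duxf3 were 0. H3K27ac regions with H3K9me3 were 7.97% and 8.24% when 50% of the shorter region had to overlap, and 9.84% in doxorubicin at the stricter q. Regions within 500 bp of an input region were 1.70% and 1.22% for H3K27ac, 2.45% and 1.87% for H3K9me3, and 38.9% for the untagged ChIP. Of 418 further gene list values 313 stayed within 1.5 times and 105 did not. The cause of these changes was not tested beyond the settings named.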

Other observations

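The X chromosome differed from the autosomes in both marks, a comparison made after seeing the data. H3K9me3 regions on X numbered 3282 in vehicle and 5362 in doxorubicin, a ratio of 1.63, above the 1.19 to 1.45 of the 19 autosomes, and their covered length was 3.47 and 4.97 Mb. H3K27ac regions on X numbered 1280 and 1262, a ratio of 0.986, below the autosomal 1.19 to 1.48. The low H3K27ac ratio was not particular to X. On Y, with few regions, it was 0.919 (62 and 57 regions). The H3K9me3 ratio on Y was 1.16 (241 and 280 regions), below that of the autosomes. The 4 windows of 1 Mb with the largest H3K9me3 gain in regions were all on X, at clusters of Btbd35f genes, and the one starting at 33000001 went from 100 to 234 regions. Next came a window on chromosome 12 from 20000001, with 169 and 259 regions, the Scgb secretoglobin cluster on chromosome 7 with 71 and 159, the window of the Zscan4 genes with 124 and 203, and the Klra receptor cluster on chromosome 6 with 51 and 127.

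The Zscan4 cluster, 9 genes and pseudogenes of the 2-cell-like state between 10794241 and 11614112 on chromosome 7, held 122 H3K9me3 regions in vehicle and 232 in doxorubicin. They covered 146 and 247 kb with a mean fold enrichment of 5.91 and 6.32, and p53 had 0 regions there. The window with the largest gain in H3K27ac regions, on chromosome 8 from 122000001 with Zfpm1, Piezo1 and Cdt1, went from 101 to 218. The p53 region of highest −log10 q, on chromosome 7 from 79954463 to 79955699, had a pileup of 7516 against 30.1 in the untagged list, 0.400% as high, both scaled to the input. Where H3K9me3 overlapped a p53 region, 48.5% of vehicle and 52.0% of doxorubicin cases had a summit within 100 bp of the p53 summit. Of p53 regions with vehicle H3K9me3, 65.2% had a summit outside gene bodies, against 41.5% of those without. Unlike the shares outside genes given above, these include summits outside a gene but within 1000 bp of its end.

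For the patterns below, the tests at a depth-scaled cut-off, of merging within 5000 bp, of a leak of p53 fragments and of the input list were chosen after the data were seen. The bound for merging was written before its ratios were computed. More regions were listed after doxorubicin for both marks although those libraries had fewer fragments. A lower cut-off would bring the counts together at a common threshold, but at 1 fragment per 1000000 the ratio of doxorubicin to vehicle regions was 1.35 for H3K27ac and 1.44 for H3K9me3. Splitting of the same domains by gaps of up to 5000 bp would end on merging, but after it the ratios were 1.29 and 1.18. Before merging they were 1.37 and 1.30, so such splitting may account for part of the excess. Splitting by wider gaps was not tested and stays open. For H3K27ac the ratio fell to 1.03 at a cut-off 5 times as high, while for H3K9me3 it was 2.38. At 10 times the regions numbered 122 in vehicle and 134 in doxorubicin for H3K27ac, and 137 and 186 for H3K9me3. A difference in ChIP efficiency between libraries may account for part of it and stays open, since pooled lists give no spread, as does an effect of doxorubicin.

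H3K27ac at p53 regions was found far more often in doxorubicin only than in vehicle only. A longer doxorubicin list would act on all regions alike, but with equal list lengths 37.2 p53 regions were in doxorubicin only for each in vehicle only. A leak of p53 ChIP fragments in proportion to the p53 signal that reached the 2717 weakest regions, of which 28.9% had the mark in doxorubicin only against 5.47% after a move by 10 kb, would reach nearly all of the strongest, yet of the 1110 strongest without vehicle H3K27ac 71.4% had it in doxorubicin. Among regions without vehicle H3K27ac, the shares from the strongest to the weakest group were 71.4%, 57.4%, 47.3% and 42.6%, a rise with the p53 signal. A leak as part of the cause at the strongest regions stays open. A candidate explanation is that p53 binding after DNA damage goes with acetylation of nearby histones, a hypothesis that cells without p53, not analysed here, would address. It would bear on few of the doxorubicin-only H3K27ac regions, of which 94.0% lay away from p53 regions.

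H3K9me3 at p53 regions, 17.8% of them in vehicle, joins a mark of heterochromatin to a transcription factor. The input list held 4 of these 1930 regions (0.207%), so regions listed in the input make up little of that share. The selection set this low number in advance, so it cannot exclude a part for signal without an antibody. The p53 list was called against the input, and removing untagged regions took out 191 of its 199 regions in the input list. A leak in proportion to the p53 signal is not the cause at the weakest p53 regions, where the share was 17.8%, as it would reach nearly all of the strongest, where it was 35.9%. At the stronger regions a leak cannot be told apart: of all 11282 p53 regions, including those in the untagged list, 2257 had vehicle H3K9me3, and the untagged list held 14.5% of these, between the bounds of 10% and 50%, with a higher pileup needed for its depth (0.968 against 0.500 fragments per 1000000). Carry-over of accessible chromatin also cannot be told apart: p53 regions without either mark in vehicle gained H3K9me3 in 8.69% of those gaining H3K27ac and 5.98% of the others, a ratio of 1.45 against the 1.5 set beforehand. Repeated elements that carry both may also be involved and were not tested, as repeat annotation was not used here.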
